A study of Mus musculus with 5 samples.

How the data were processed

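RNA was hybridised to 5 one-colour (Cy3) Agilent mouse arrays, 1 for each of the E13.5, P0 and 8-week kidney and the 2-week and 4-week kidney bud transplant. RNA was prepared with a column kit, checked for quality and labelled with a low-input one-colour kit, per the labels' protocols. The composition of the buds and the site of transplantation are not given in the sources used here. The groups were taken from the sample titles.

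The deposited scanner files give each spot's intensity, background-subtracted and detrended by Agilent Feature Extraction 10.7.3.1, per the file headers. Each holds 44397 spots, of which 43020 are not controls. The deposited gene table of the authors holds log2 values, and its title line names a 75th percentile shift. Set against the scanner values, 99.6% of its values were within 0.01 of the log2 processed signal without any shift, averaged over a gene's probes and centred to a median of 0 in each of 30224 rows. After a shift by the 75th percentile 18.2% were. The table therefore carries no percentile shift, and its column medians were 0.05 (E13.5), 0 (P0), 0 (2-week transplant), -0.08 (4-week transplant) and 0 (8-week kidney). The base of its logarithm is not stated but follows from this match.

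The main value was log2 of the processed intensity minus log2 of the array's 75th percentile over spots that are not controls. These percentiles were 1619.7 (E13.5), 1720.1 (P0), 1713 (2-week transplant), 1504 (4-week transplant) and 1170.2 (8-week kidney). Spots marked as outliers on any array were left out, and no spot was saturated. The other deposited columns used were flags per spot for signal well above background, saturation and outliers, per the file headers. Spots of a probe were averaged, and the probe with the highest mean level over the 5 arrays stood for its gene. Of 39414 probes, 31781 were named through the gene identifier in the authors' table and RefSeq names (GRCm38), 2026 kept the authors' symbol, 19 were named through an accession and 5588 stayed unnamed. The design's grid is on the mm9 build, so no coordinates are given. Of 24563 genes, 7202 had more than 1 probe. In 228 pairs of gene and array the probe used was not well above background while another probe of the gene was.

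Where the probe was well above background on 1 array only, the dim side entered at the higher of its own value and the lowest value well above background on that array, and the fold is given as "at least". A bound that would have turned the direction entered as 0. Genes not well above background on either array were left out. Replicate spots of a probe on 1 array had a median SD of 0.0513 to 0.0605 log2 units, which covers spot error but neither labelling nor animals. The number of arrays limits the precision. Counts used a 4-fold difference. Before the data were examined, 39 gene lists with 398 matched and 2 unmatched members were fixed, and for each the members at least 2-fold apart, the median difference and its percentile among 10000 random lists matched on mean level were computed. Bounds enter these medians. The 6 lists named in the closing observations (brown fat, urothelium, choroid plexus, adrenal medulla, other steroidogenic genes and fetal skeletal muscle) were written after values of many of their members were seen.

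Genes were named by a rule fixed beforehand: the 10 largest positive and 10 largest negative differences per main comparison among genes well above background on both arrays, leaving out gene-model names, and any member of a gene list, with those furthest apart or against their list as examples. A few genes that this rule allows are not reported here. The steps were tested on simulated data for the 4-week against the 2-week transplant (18111 genes compared, 50 genes per size and direction). Of genes changed 8-fold, 100% were called at 4-fold in each direction, of genes changed 3-fold 2% (up) and 0% (down), and 0 unchanged genes were called. The changed genes all lay above the median level. The simulated noise was small against a 4-fold difference and held no variation between animals, labellings or slides. These rates therefore follow from the setting and check the computation only. They do not show how often real single arrays give false calls.

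Alternatives fixed beforehand were normexp background correction (offset 50), quantile normalization, the authors' table, the mean over a gene's probes, other background filters, 2-fold and 8-fold thresholds and Spearman's rho. The files hold no mean signal, so normexp used the median signal and median background. Its fit on the E13.5 array gave a background mean of -992, against 20.7 to 27.5 on the other arrays, and distorts every comparison with that array. A maximum likelihood fit was then tried and gave -1022, and after that a normexp correction with the 153 negative control spots of each array, which gave a usable fit. Both were chosen after seeing the data. With 1 array per group, slide could not be fitted as a term. The 2-week transplant against E13.5 lies within slide 1, and comparisons among the P0 kidney, the 8-week kidney and the 4-week transplant within slide 2. The other comparisons cannot be run within a slide. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.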

Results

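Gene expression was measured on 5 one-colour microarrays of C57BL/6 mouse tissue, with 1 array in each of 5 groups. The groups were kidney at the embryonic stage E13.5, kidney on the day of birth (P0), kidney at 8 weeks of age, and tissue recovered 2 weeks or 4 weeks after transplantation of a kidney bud. No group had a replicate, so no difference has a replicate check or a p-value, and every value describes single arrays. Of 24563 genes, 19366 were well above background on at least 1 array. The share of gene spots well above background was 63.4% for the E13.5 kidney, 65.7% for the P0 kidney and 60.9% for the 8-week kidney. It was 69.1% for the 2-week and 68.6% for the 4-week transplant. The E13.5 kidney and the 2-week transplant lay on slide 1, and the other arrays on slide 2. In comparisons across slides, slide and group cannot be told apart. The Y-linked Ddx3y was not well above background in the P0 kidney, nor the X-linked Xist in the 8-week kidney, while the other arrays carried both. In comparisons with these kidneys, sex and group cannot be told apart either. Each gene list was also set against 10000 random lists of the same size and signal level, and a percentile near 100 or 0 means a median above or below nearly all of them.

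The comparison of the P0 with the E13.5 kidney follows the kidney from mid-gestation to birth. Genes of the mature nephron were higher at P0. All 22 measured genes of the proximal tubule, the segment that reabsorbs most of the filtrate, were at least 2-fold higher, with a median log2 difference of 6.75 (percentile 100). Among them, Fbp1 (gluconeogenesis) was 629.6-fold, Miox (inositol breakdown) 613-fold and the phosphate transporter Slc34a1 at least 623-fold higher. Other genes among the largest differences were Hsd3b4 (916-fold), Cyp2d26 (814-fold), Spink1 (758-fold), Gsta2 (423-fold), Dao (332-fold) and Hdc (271-fold, histamine synthesis).

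The other nephron lists also lay higher at P0. In the loop of Henle list, 9 of 10 genes were higher (median 4.62), with Umod (uromodulin) at 209-fold and Kcnj1 at least 176-fold, while Egf was within 2-fold. In the list of collecting duct principal cells 8 of 10 were higher (median 3.97), led by the water channels Aqp2 (189-fold) and Aqp3 (156-fold). In the list of intercalated cells 8 of 9 were higher (median 3.70, or 0 with a normexp background correction). In the distal tubule list 6 of 9 were higher (median 1.31), including the calcium-binding S100g (331-fold). Of the podocyte genes, which build the glomerular filter, 7 of 11 were higher (median 2.21), with Ptpro at 15.8-fold. Of the renal endocrine list 7 of 8 were higher, with Ren1 (renin) at 19.2-fold.

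Lists of the early kidney did not all differ in the same direction at P0. Of the fetal growth genes 9 of 12 were at least 2-fold lower (median -1.84), with Lin28b, a regulator of developmental timing, 18.8-fold and Hmga2 12.8-fold lower. Of the nephron progenitor genes 7 of 14 were lower, such as Osr1 (8.09-fold) and Six2 (2.35-fold), and Cited1 and Gdnf were within 2-fold. The ureteric bud tip list had 1 of 10 genes lower and 9 within 2-fold, the proliferation list 5 of 13 lower and the fetal stroma list 5 of 10 lower, with Foxd1 8.63-fold lower. The early nephron list had 6 of 11 genes higher, 0 lower and a median of 1.03, which turned negative with a normexp background correction. Among the largest negative differences were Actc1 (68.6-fold), Myl1 (37.6-fold), Crabp1 (31.9-fold), Clstn2 (31.4-fold), Ebf3 (26.9-fold), Myh3 (25.3-fold), Tmem202 (20.7-fold), Foxf1 (19.8-fold) and Asic4 (18.3-fold). In all, 1096 genes were at least 4-fold higher and 322 lower among 17572 compared. These arrays lay on different slides. With a normexp background correction the split became 304 higher and 3207 lower, and that fit gave a background mean of -992 on the E13.5 array. With background from the negative controls, which could be fitted, 765 and 150 genes were higher and lower.

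The 8-week kidney gives the adult reference. All 22 proximal tubule genes were higher than at E13.5, with a median log2 difference of 11.31 (percentile 100). Miox was 8853-fold, Cyp2e1 8618-fold, Slc27a2 7824-fold, Fbp1 3405-fold and the organic anion transporter Slc22a6 3219.6-fold higher. All 10 loop of Henle genes were higher (median 6.81), with Umod at 4140.4-fold and Egf at 746-fold. Spink1 (6969-fold), Dnase1 (6289.9-fold) and Nat8 (3201-fold) were also among the largest positive differences.

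The distal tubule list had 8 of 9 genes higher (median 2.66), the principal cell list 8 of 10 (median 3.51) and the intercalated cell list 9 of 9 (median 4.63). The podocyte list was mixed in size, with 6 of 12 genes higher (median 1.21). Nphs1 (nephrin) was 14.3-fold higher and Wt1, which also marks progenitors, 26.8-fold lower. Of the fatty acid oxidation genes 11 of 12 were higher (median 4.39), led by Cyp4a10 (497-fold) and Ehhadh (342-fold). Antigen presentation (9 of 10, median 3.71) and interferon response genes (8 of 9, median 2.75) were also higher than at E13.5. The kidney injury list had a median of 1.07, whose sign turned with a normexp background correction.

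All 13 cell cycle genes were lower at 8 weeks, with a median of -6.41 and Plk1, a mitotic kinase, 206-fold lower. All 12 fetal growth genes were lower (median -7.08), among them the imprinted genes Mest (1386-fold) and Dlk1 (1098-fold). Of the nephron progenitor genes 11 of 14 were lower (median -3.97), with Cited1 482-fold lower, and Crym (7.30-fold) and Eya1 (2.97-fold) went the other way. Fetal stroma genes (8 of 10 lower, median -3.94), ureteric bud tip genes (9 of 10, median -2.11) and extracellular matrix genes (10 of 12, median -3.14) were lower too. Capn6 (356-fold), Cdca7 (313-fold), H1f5 (270.4-fold), Dpysl4 (256-fold), Shisa3 (231-fold) and Mfap4 (203-fold) were among the largest negative differences. The arrays lay on different slides, and 2483 genes were at least 4-fold higher and 2231 lower among 17637. The split depended on scaling, with 1852 higher and 3083 lower in the authors' table, which carries no percentile shift, and 1437 and 3944 with a normexp background correction, or 2058 and 1594 with background from the negative controls. Within slide 2, 1577 genes were higher and 1651 lower in the 8-week than in the P0 kidney, or 964 and 2441 in the authors' table.

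The question for the transplants was how far development-related expression in kidney buds follows that of the kidney. In the 2-week transplant, the medians of all 6 nephron segment lists lay above the E13.5 kidney, but with a normexp background correction that of the loop of Henle was 0 and that of the distal tubule negative. Set against the P0 kidney, which lay on the other slide, 15 of 22 proximal tubule genes were lower (median -3.01). Medians were also negative for the loop of Henle (-1.49), principal cells (-1.40) and distal tubule (-0.47). They were positive for podocytes (1.32) and intercalated cells (0.55). Against the E13.5 kidney, all 21 measured proximal tubule genes were at least 2-fold higher, with a median of 4.66 (percentile 100). Kap was at least 468-fold, Pck1 (gluconeogenesis) at least 415-fold and Cyp2e1 209.8-fold higher. Fat also expresses Pck1 and Cyp2e1, and adipocyte genes were higher on this array. Of the podocyte genes 9 of 12 were higher (median 2.86), with Ptpro at 64.5-fold and Nphs1 at 29.9-fold, and Wt1 was 2.96-fold lower.

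Of the intercalated cell genes 9 of 9 were higher (median 4.29), of the principal cell genes 7 of 10 (median 2.57) and of the loop of Henle genes 8 of 10 (median 2.95). Aqp2 was 18.1-fold, Kcnj1 at least 178-fold and Umod 43.6-fold higher. The distal tubule list had 4 of 9 genes higher, with Klk1 at least 682-fold, and Calb1, which the ureteric bud also expresses, was 2.67-fold lower. Of the renal endocrine genes 6 of 8 were higher, with Ren1 at 15.0-fold, and the list median of 2.48 was 0 with that correction.

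All 10 ureteric bud tip genes were lower (median -2.33), with Wnt11 9.52-fold lower, as were 10 of 14 progenitor genes (median -1.71). The fetal renal stroma list was mixed, with 5 of 10 genes lower and 2 higher, Smoc2 (5.22-fold) and Dkk2 (4.04-fold), and a median of -0.88. Gdnf, the signal to the ureteric bud, was 159.8-fold and Cited1 74.5-fold lower. All 13 cell cycle genes (median -3.15) and 11 of 12 fetal growth genes (median -2.47) were lower, with Hmga2 at 246-fold, Igf2bp1 at 85.5-fold and Igf2bp3 at 84.0-fold. The early nephron list had 5 of 11 genes lower, such as Lhx1 (34.6-fold), and Irx1 higher (2.77-fold). Syt10 (682-fold), Mirg (269-fold), Actc1 (104-fold), Crabp1 (82.9-fold) and Ntsr1 (82.5-fold) were the other largest negative differences. The probes of Mirg and Lhx1 differed in size, with log2 differences from -8.07 to -1.80 and from -5.11 to -2.50.

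Genes of other cell types were higher in the 2-week transplant. All 8 adipocyte genes were higher (median 7.26, percentile 100), including Cfd (at least 4591-fold) and Adipoq (at least 885-fold), and the largest differences included Cox8b (1357-fold), Cidea (549.7-fold) and Gpd1 (285-fold). Of the macrophage genes 11 of 12 were higher (median 4.29), with Lyz2 at 292-fold. Antigen presentation (9 of 10, median 5.81), interferon response (10 of 10, median 4.49) and kidney injury genes (8 of 10, median 3.19) were higher. Smooth muscle (7 of 10, median 3.56), endothelial (11 of 12, median 1.56) and matrix genes (9 of 12, median 1.75) were higher as well. The P0 kidney also lay above E13.5 for smooth muscle (7 of 10, median 2.29) and endothelial genes (7 of 12, median 1.14). So it did for interferon response (7 of 8, median 2.76, or 0 with normexp) and antigen presentation genes (6 of 9, median 1.89). Against P0, on the other slide, the 2-week medians were 0.71 (smooth muscle), 0.38 (endothelium), 1.93 (interferon), 3.57 (antigen presentation), 3.47 (macrophage) and 1.62 (matrix). Against E13.5, 7 of 8 bone genes were higher (median 2.76, or 0 with a normexp background correction), with Bglap (osteocalcin) at least 101-fold and Ibsp at least 87.0-fold. Of the glia genes 6 of 10 were higher, with Gfap at least 247-fold, S100b at 127-fold and Olig1 at least 34.8-fold. The complement genes C2 (486-fold), C4b (453-fold) and C3 (359.8-fold, with log2 differences of 6.00 to 8.49 over its probes), and Ptgds (1254-fold), Htra1 (317-fold) and Ecrg4 (300.0-fold) were also among the largest positive differences. The 2-week transplant and the E13.5 kidney lay on slide 1, and 2070 genes were at least 4-fold higher and 989 lower among 18264. With that correction 606 were higher and 3305 lower, and with background from the negative controls 1515 and 670.

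The 4-week transplant differed from the E13.5 kidney in the same 6 nephron segment lists, by smaller medians than the 2-week transplant did. The renal endocrine list had a median of 3.20 over 6 measured genes, 5 of them higher, against 2.48 over 8 genes at 2 weeks. With a normexp background correction these medians were 0.32 and 0. They rest on different members and show no rise between the graft times. Set directly against the 2-week transplant, 8 genes had a median of -0.54, with 2 higher and 2 lower. The higher genes included Akr1b7, which the closing observations also count among other steroidogenic genes. Of the proximal tubule genes 20 of 21 were higher (median 3.16, percentile 100). With a normexp background correction, whose fit distorts comparisons with the E13.5 array, that median was 0. It stayed positive with background from the negative controls. Kap was at least 497-fold, Slc27a2 48.5-fold, Miox 16.8-fold and Slc5a2 at least 8.47-fold higher. Cyp2e1 (1993-fold) and Pck1 (at least 1576-fold), which fat also expresses, had the largest differences and are not typical of the list, as they were the only 2 of its genes at least 2-fold higher at 4 than at 2 weeks. Podocyte genes were higher in 8 of 12 cases (median 2.25), loop of Henle genes in 7 of 10 (median 2.44, or 0 with that correction) and intercalated cell genes in 8 of 9 (median 3.66). The principal cell list had 6 of 10 genes higher and a median of 1.31, whose sign turned with a normexp background correction, as did that of the distal tubule list (0.71). In the distal tubule list 4 of 9 genes were higher, with S100g at 48.5-fold, and Calb1 was 19.2-fold lower.

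Progenitor genes (11 of 14 lower, median -2.83), bud tip genes (9 of 10, median -2.48), cell cycle genes (13 of 13, median -3.53) and fetal growth genes (12 of 12, median -3.94) were lower. The largest negative differences were Hmga2 (387-fold), Crabp1 (171-fold), Gdnf (163-fold), Cited1 (153-fold), Sox11 (132-fold), Dusp9 (98.8-fold), Ntsr1 (86.9-fold), Igf2bp3 (86.1-fold), Has2 (84.0-fold) and Igf2os (73.5-fold).

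All 8 adipocyte genes were higher than at E13.5 (median 8.75), and the brown fat gene Cox8b (4121-fold), Cidea (1854-fold), the lipid droplet gene Plin4 (1193-fold) and Gpd1 (687-fold) were among the largest differences. All 7 adrenal cortex genes were higher (median 9.87, percentile 100), including Star, which carries cholesterol into mitochondria (1244-fold), and Hsd3b1 (1781-fold). Macrophage (12 of 12, median 3.78), neutrophil (8 of 9, median 3.63), antigen presentation (9 of 10, median 6.34) and interferon response genes (10 of 10, median 4.90) were higher, and C3 was 1332-fold (log2 differences of 7.76 to 10.38 over its probes), Hp (haptoglobin) 584-fold and C4b 583-fold higher. Neutrophil genes were also higher at P0 than at E13.5 (6 of 8, median 2.53), but not with a normexp background correction. Glia (7 of 9, median 2.13) and bone genes (4 of 6, median 1.92) were higher in the 4-week transplant too, though neither median held with that correction. The 4-week transplant and the E13.5 kidney lay on different slides, and 2335 genes were at least 4-fold higher and 1259 lower among 18320, or 748 and 3312 with a normexp background correction and 1741 and 899 with background from the negative controls. Against the P0 kidney of its own slide, the 4-week transplant had 1597 genes higher and 804 lower, and its proximal tubule genes had a median of -4.08.

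**Figure D1:**
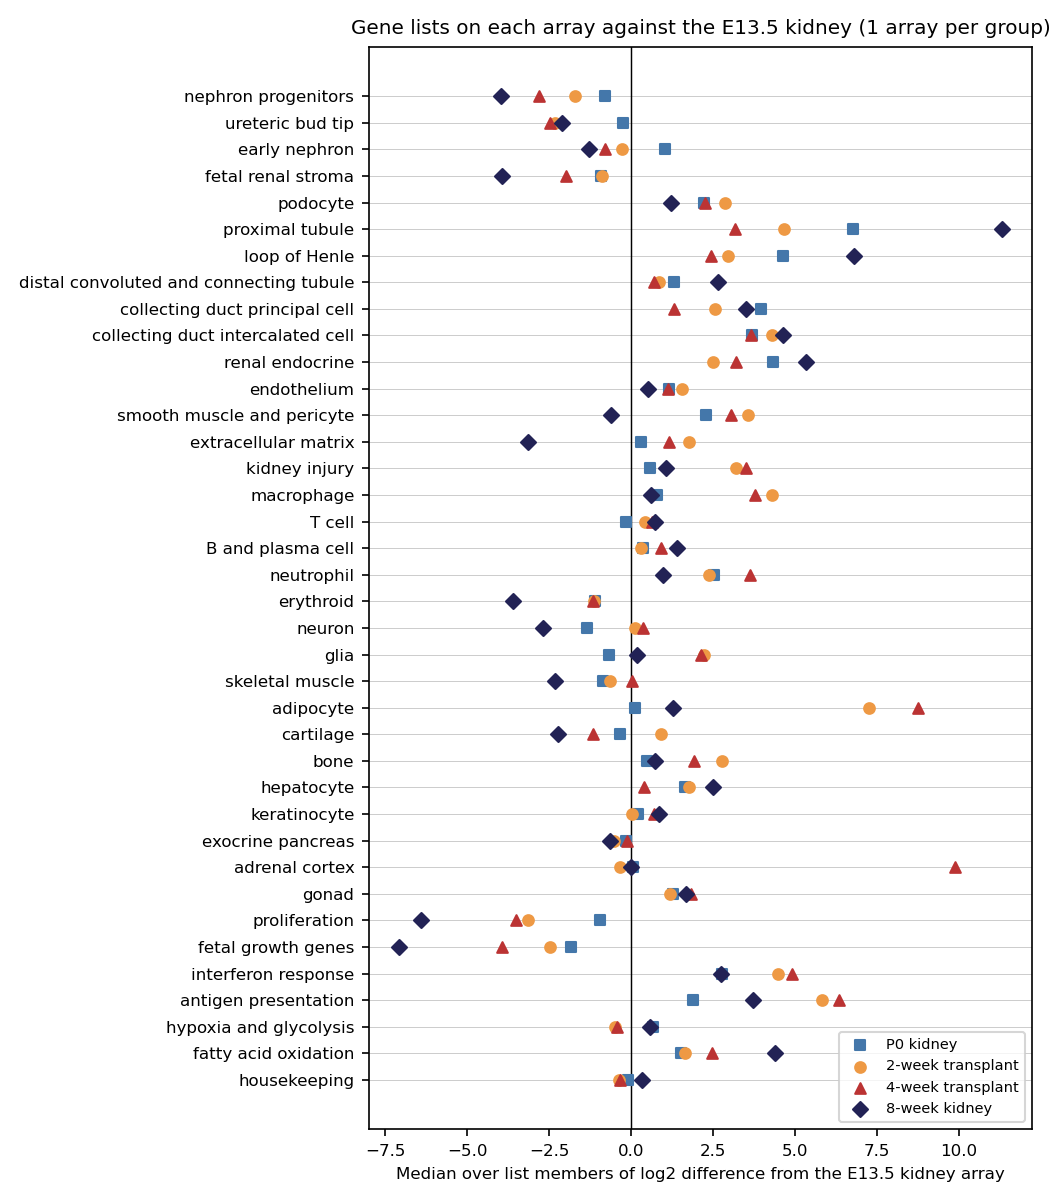
Each point is the median over the measured genes of 1 list of the log2 difference between 1 array and the E13.5 kidney array, by list on the vertical axis, for the P0 kidney, the 8-week kidney and both transplants (1 array each, so no error bars), with the sex-linked list left out. Proximal tubule genes lie at 11.31 in the 8-week kidney and at 4.66 and 3.16 in the 2-week and 4-week transplants, and adrenal cortex genes lie at 9.87 in the 4-week transplant.

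The comparison of the 4-week with the 2-week transplant shows what differed between the graft times. All 7 adrenal cortex genes were higher at 4 weeks, with a median of 10.16 (percentile 100): Star was 1574-fold, Cyp21a1 526-fold, Hsd3b1 at least 5262-fold and the steroidogenic regulator Nr5a1 87.8-fold higher. All 8 adipocyte genes lay higher, 7 of them at least 2-fold. Of the neutrophil genes 5 of 9 (median 2.02) and of the fatty acid oxidation genes 7 of 12 (median 1.05) were higher, with S100a8 at 8.01-fold and Ppara at 5.15-fold. Other large positive differences were Akr1c18 (914-fold), Mgarp (649.9-fold), Ttr (transthyretin, 334-fold), Fam25c (216-fold), Ly6d (194-fold), Sprr1a (143-fold), Syt10 (127-fold) and Upk1a, a coat protein of the urothelium (115-fold).

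Nephron lists had negative medians, from -0.60 for the proximal tubule and -0.73 for podocytes to -1.08 for the distal tubule. In the proximal tubule list 9 of 21 genes were at least 2-fold lower, such as Slc5a2 (8.74-fold) and Miox (4.26-fold), and Cyp2e1 (9.50-fold) and Pck1 (3.80-fold) were higher. In the principal cell list Aqp2 was 5.38-fold lower. Aqp4 of that list was 15.4-fold lower, beside the glia gene Gfap (18.8-fold), and which cells carried Aqp4 cannot be told. The loop of Henle, principal cell and intercalated cell medians were -0.92, -0.77 and -0.84. Of the bone genes 6 of 8 (median -2.23), of the cartilage genes 6 of 7 (median -1.48) and of the glia genes 4 of 10 were lower. In the glia list 2 genes were higher, and the median was -0.54. The largest negative differences were Gpr17 (33.2-fold), Tgm5 (24.7-fold), Spp2 (23.1-fold), Gfap (18.8-fold), Bglap (18.1-fold), Bglap2 (16.8-fold), Bglap3 (15.0-fold), Ibsp (log2 difference -3.76), and Vxn (16.9-fold). Bglap, Bglap2 and Bglap3 are near-identical copies that their probes may not tell apart. The arrays lay on different slides, and 451 genes were at least 4-fold higher and 189 lower among 18493, or 353 and 238 in the authors' table, 215 and 60 with a normexp background correction and 246 and 71 with background from the negative controls.

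**Figure D2:**
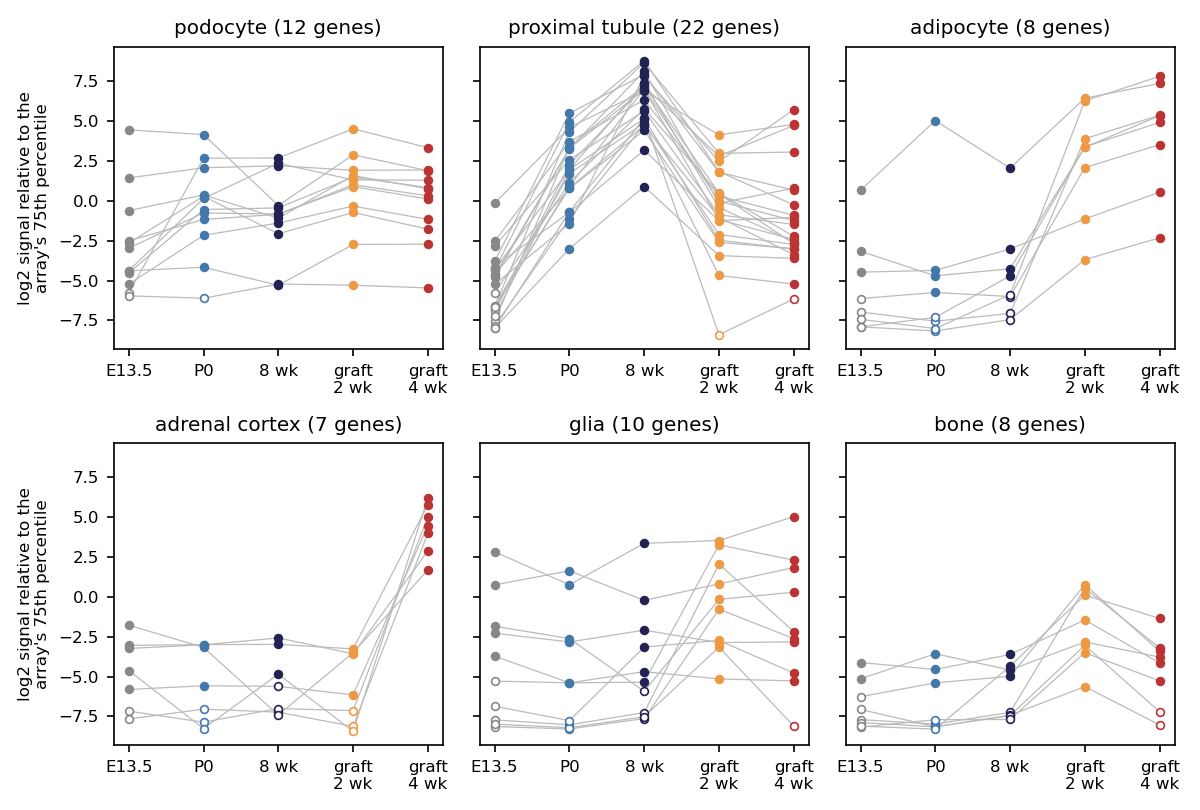
Each point is the log2 signal of 1 gene on 1 array relative to that array's 75th percentile, for 6 gene lists, with the arrays along the horizontal axis, grey lines joining the points of a gene and open points not well above background. Star lies at 4.47 in the 4-week transplant and -6.15 in the 2-week transplant, and Gfap at 2.05 in the 2-week and -2.18 in the 4-week transplant.

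The comparison of the 4-week transplant with the 8-week kidney sets the graft against the adult organ. Xist was well above background in the graft only, so a difference in sex cannot be told apart from one of graft or age. All 22 proximal tubule genes were lower in the graft, with a median of -7.52 (percentile 0), including the urate transporter Slc22a12 (1025-fold) and Acsm2 (974-fold). Loop of Henle (9 of 10 lower, median -4.39), distal tubule (7 of 9, median -3.20), principal cell (6 of 10, median -1.63) and intercalated cell genes (6 of 9, median -1.60) were lower by less. The podocyte list had a median of 0.80, with 5 of 12 genes higher, among them Wt1 (4.55-fold), and Clic5 2.09-fold lower. Egf was 421-fold and the vitamin D hydroxylase Cyp24a1 at least 309.7-fold lower. Dnase1 (3701-fold), Serpinf2 (3037-fold), Ugt2b38 (2960.2-fold), Slc17a3 (1880.2-fold), Ugt3a1 (1227-fold), Akr1c21 (1158-fold), Ugt2b37 (1082-fold) and Acsm1 (1052-fold) had the other largest negative differences.

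Genes higher in the graft included all 8 adipocyte genes (median 9.04), with Cidec at 1059.6-fold (log2 differences of 6.82 to 10.05 over its probes) and Retn at 580.0-fold, and all 7 adrenal cortex genes (median 9.36), with Hsd3b1 at 2082-fold and Cyp21a1 at 433-fold. Matrix genes (11 of 12, median 4.35), such as Col3a1 (98.8-fold) and Timp1 (299.9-fold), macrophage genes (11 of 12, median 3.50) and smooth muscle genes (9 of 10, median 3.05) were higher. Cell cycle (10 of 12, median 3.01), fetal growth (8 of 11, median 3.03) and fetal stroma genes (8 of 10, median 2.46) lay above the adult kidney, with H19 at least 305-fold and Dlk1 at 292-fold. Of the kidney injury genes 6 of 10 were higher, with Lcn2 at 33.0-fold, and Havcr1, which was well above background in the adult kidney, was 79.4-fold lower. Ttr (2451-fold), Hp (1119-fold), Rbp4 (616-fold), Ccl8 (495-fold), Mrap (435-fold) and Apod (427-fold) were also among the largest positive differences. Both arrays lay on slide 2, and 2150 genes were at least 4-fold higher and 1428 lower among 18309, or 2618 and 1056 in the authors' table, 1236 and 1142 with a normexp background correction and 1358 and 1185 with background from the negative controls.

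**Figure D3:**
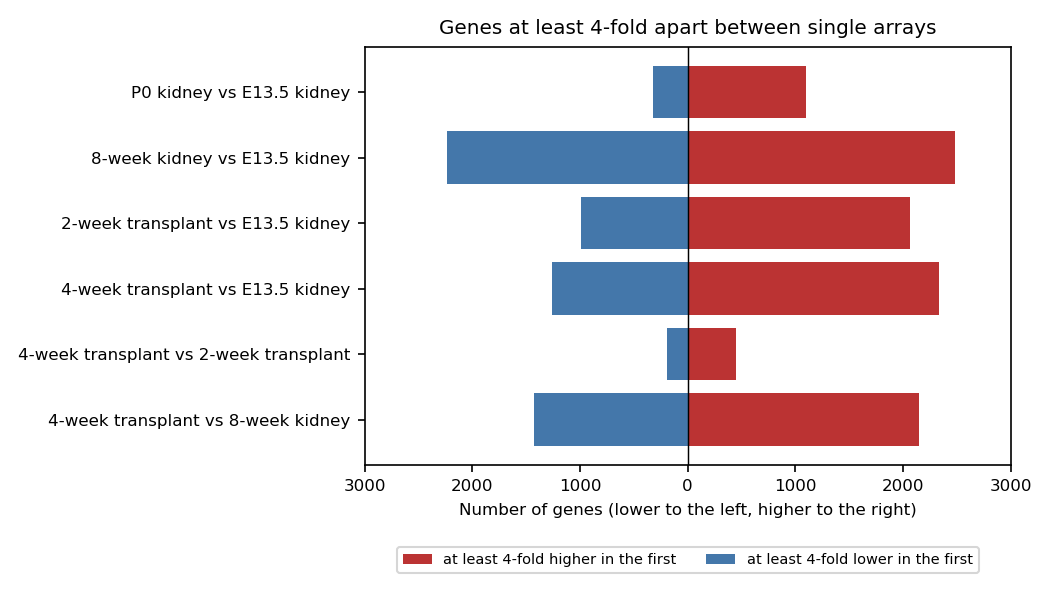
Bars give the number of genes at least 4-fold higher (right) or lower (left) on the first than on the second array of each comparison, between single arrays and so with no error bars. The bars for the 8-week against the E13.5 kidney reach 2483 and 2231 genes, and those for the 4-week against the 2-week transplant 451 and 189.

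The position of each array between the E13.5 and the 8-week kidney was described by the genes at least 4-fold apart between those kidneys. These genes may come from any cell type, and the transplants also carried fat and macrophage genes, so the shares do not measure nephron maturation. Against E13.5, proximal tubule medians were 6.75 at P0 and 4.66 and 3.16 in the transplants. The loop of Henle, distal tubule and principal cell medians were also highest at P0, and the podocyte and intercalated cell medians at 2 weeks. For the 2483 genes higher at 8 weeks, the median gene had covered 36.6% of the log2 difference in the 2-week transplant (quartiles 11.3% and 69.0%), 44.8% in the 4-week transplant (quartiles 15.0% and 79.0%) and 35.9% in the P0 kidney (quartiles 15.4% and 58.5%). For the 2231 genes lower at 8 weeks the medians were 46.3% (quartiles 13.0% and 73.1%), 57.8% (quartiles 25.7% and 82.5%) and 25.1% (quartiles 11.4% and 41.7%). With a normexp background correction the shares were 24.3%, 33.7% and 31.5% for the genes higher and 87.3%, 89.2% and 88.3% for the genes lower at 8 weeks, in the same order. With background from the negative controls the latter were 51.7% and 63.7% in the transplants, and the P0 share stayed within its interval over genes. The E13.5 array enters both sides of each share, so an error on that array moves all of them. Across 19366 genes, which are not independent replicates, Pearson's r of the 2-week transplant was 0.911 with the P0, 0.862 with the E13.5 and 0.823 with the 8-week kidney. For the 4-week transplant r was 0.885, 0.836 and 0.825, and between the transplants 0.954. Between the P0 and the 8-week kidney r was 0.863, and not all of the 10 pairs of arrays are given.

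The remaining lists were less even. Of the hypoxia and glycolysis genes 7 of 11 were lower in the 2-week transplant than in the P0 kidney, which lay on the other slide (median -1.03). Against E13.5, 7 of 11 were within 2-fold at 2 weeks, with 2 higher and 2 lower (median -0.49). At 4 weeks 4 were higher and 2 lower (median -0.43). With a normexp background correction the T cell, B cell and neuron medians below turned negative at both times, and the keratinocyte median at 2 weeks did so too and with quantile normalization. The T cell list had medians of 0.43 and 0.62 in the 2-week and 4-week transplants against the E13.5 kidney, with Cd2 at least 12.7-fold and at least 9.02-fold, and the B cell list 0.31 and 0.90. Medians of the neuron list were 0.11 and 0.37, of the skeletal muscle list -0.64 and 0.02, of the exocrine pancreas list -0.52 and -0.12 and of the gonad list 1.18 and 1.83 (both 0 with a normexp background correction). The keratinocyte list had medians of 0.03 and 0.69, with Krt5 (185-fold) and Sprr1a (529-fold) higher at 4 weeks. The hepatocyte list had 1.75 and 0.40, both of which turned negative with a normexp background correction and the second also with quantile normalization, and Afp was at least 14.5-fold lower at 4 weeks. The erythroid list had -1.14 and -1.15, the second of which was 0.37 over genes well above background on both arrays. Housekeeping genes had medians of -0.36 and -0.35 against E13.5, the signs of which turned with a normexp background correction and at 2 weeks also with quantile normalization.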

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

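All tests in this part, and the adrenal medulla list, were chosen after the results they concern had been seen. With 1 array per group, the differences between graft times below were not tested. Gene lists are given where the median difference from the E13.5 kidney had opposite signs at 2 and 4 weeks and the medians were at least 1 log2 unit apart.

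The adrenal cortex list had a median of -0.34 in the 2-week and 9.87 in the 4-week transplant, so the 2-week minus the 4-week value was -10.21. A difference between slides is argued against, since within slide 2 the smaller list median of the 4-week transplant against the P0 and the 8-week kidney was 9.36 and the lowest member difference 4.86. Adrenal gland tissue in the sample is a candidate explanation: the adrenal medulla list, the other part of the gland, had a median of 1.75 at 4 against 2 weeks, with 7 of 10 genes at least 2-fold higher, such as Chga (22.8-fold) and Dbh (5.26-fold), and with Dbh at 1.42 and Chga at 0.49 in the 4-week transplant relative to the 75th percentile. All 10 medulla genes and 5 of 7 cortex genes were also well above background in at least 1 of the kidneys. Whether adrenal cells came along with the E13.5 kidney stays open: 5 of the 7 cortex genes were well above background on that array, 2 of them at least 2-fold higher than in the P0 kidney, and a small share of cells can lie below background, while a biological difference between the graft times was not tested and stays open too.

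The cartilage list had a median of 0.91 at 2 weeks and -1.16 at 4 weeks against E13.5, a difference of 2.07, with Comp higher (66.2-fold and 61.3-fold) and Col2a1 lower, at both times. The first median turned negative (-1.40) with a normexp background correction, and the second was 0.49 over genes well above background on both arrays. The list of sex-linked genes, which mixes the X-linked Xist with Y-linked genes, had a difference of -1.35 between its medians of -0.81 and 0.53, the second of which was -0.90 with a normexp background correction.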

How the results depend on the processing

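The corrections by normexp with maximum likelihood and with negative controls were chosen after seeing the data, and the other alternatives before. With 1 array per group nothing could be set against a spread between replicates, so counts are given where they differed by more than 1.5 times, and shares and correlations where they left the interval over genes. Where a threshold or filter differs, it changes the genes counted by construction. For the other alternatives the cause was not tested, beyond the normexp fit on the E13.5 array.

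Of 163 list medians at least 2-fold apart, all kept their direction with quantile normalization, in the authors' table, with the mean over probes and with normexp from negative controls. Over genes well above background on both arrays 154 kept it and 9 turned. With normexp 135 kept it, 12 turned and 16 were 0, and with maximum likelihood 134, 12 and 17. No gene named among the 10 largest differences in either direction turned sign under another background correction or scaling. These genes were picked as the most extreme differences, so a turn of sign was unlikely from the start. Most of their folds moved by more than the error between spots: 118 differences did so with each normexp version, 97 in the authors' table, 91 with quantile normalization and 32 with the mean over probes. The share of genes higher among those 4-fold apart was 37.5% in the authors' table for 8 weeks against E13.5 (52.7% with the 75th percentile), 59.7% for the 4-week against the 2-week transplant (70.5%) and 71.3% for the 4-week transplant against 8 weeks (60.1%). With normexp it was 8.66% for P0 (77.3%), 26.7% for 8 weeks, 15.5% for the 2-week (67.7%) and 18.4% for the 4-week transplant (65.0%), each against E13.5. With normexp from negative controls these were 83.6%, 56.4%, 69.3% and 65.9%. The median over all genes moved with the scaling, from -0.02 to -0.49 in the authors' table for 8 weeks against E13.5, from -0.14 to 0.23 for the 4-week transplant against 8 weeks, and from -0.22 to -0.57 with normexp for the 2-week transplant against E13.5.

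With normexp background correction the count was 3511 for P0 against E13.5, 275 for the 4-week against the 2-week transplant and 2378 for the 4-week transplant against 8 weeks. The share was 24.3% (2-week transplant), 33.7% (4-week transplant) and 31.5% (P0 kidney) for genes higher at 8 weeks, and 87.3% (2-week transplant), 89.2% (4-week transplant) and 88.3% (P0 kidney) for genes lower at 8 weeks. The correlation of the 2-week transplant was 0.843 with the E13.5 kidney, 0.930 with the P0 kidney and 0.839 with the 8-week kidney, and that of the 4-week transplant was 0.826 with the E13.5 kidney, 0.908 with the P0 kidney and 0.844 with the 8-week kidney. With normexp by maximum likelihood the count was 3548 for P0 against E13.5 and 276 for the 4-week against the 2-week transplant. The share was 24.4% (2-week transplant), 33.7% (4-week transplant) and 31.7% (P0 kidney) for genes higher at 8 weeks, and 87.7% (2-week transplant), 89.4% (4-week transplant) and 88.4% (P0 kidney) for genes lower at 8 weeks. The correlation of the 2-week transplant was 0.842 with the E13.5 kidney, 0.930 with the P0 kidney and 0.839 with the 8-week kidney, and that of the 4-week transplant was 0.825 with the E13.5 kidney, 0.907 with the P0 kidney and 0.844 with the 8-week kidney. With normexp from negative controls the count was 915 for P0 against E13.5 and 317 for the 4-week against the 2-week transplant. The share was 32.7% (2-week transplant) and 39.7% (4-week transplant) for genes higher at 8 weeks, and 51.7% (2-week transplant) and 63.7% (4-week transplant) for genes lower at 8 weeks. The correlation of the 2-week transplant was 0.880 with the E13.5 kidney, 0.929 with the P0 kidney and 0.839 with the 8-week kidney, and that of the 4-week transplant was 0.855 with the E13.5 kidney, 0.906 with the P0 kidney and 0.844 with the 8-week kidney.

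With quantile normalization the share was 41.9% (4-week transplant) and 37.4% (P0 kidney) for genes higher at 8 weeks, and 60.8% (4-week transplant) for genes lower at 8 weeks. In the authors' table the share was 43.2% (2-week transplant) and 46.2% (P0 kidney) for genes higher at 8 weeks, and 41.8% (2-week transplant) and 21.6% (P0 kidney) for genes lower at 8 weeks. Over genes well above background on both arrays the count was 939 for P0 against E13.5. Without the background filter the count was 1056 for the 4-week against the 2-week transplant. At 2-fold the count was 4530 for P0 against E13.5, 9630 for 8 weeks against E13.5, 7623 for the 2-week transplant against E13.5, 8477 for the 4-week transplant against E13.5, 2733 for the 4-week against the 2-week transplant and 7477 for the 4-week transplant against 8 weeks. At 8-fold the count was 642 for P0 against E13.5, 2587 for 8 weeks against E13.5, 1430 for the 2-week transplant against E13.5, 1754 for the 4-week transplant against E13.5, 218 for the 4-week against the 2-week transplant and 1783 for the 4-week transplant against 8 weeks. Over genes 2-fold apart between the E13.5 and 8-week kidneys the share was 30.5% (2-week transplant) and 27.5% (P0 kidney) for genes higher at 8 weeks, and 57.5% (2-week transplant), 65.8% (4-week transplant) and 32.2% (P0 kidney) for genes lower at 8 weeks. Over genes well above background on all arrays used the share was 39.3% (2-week transplant), 50.1% (4-week transplant) and 37.5% (P0 kidney) for genes higher at 8 weeks, and 23.6% (P0 kidney) for genes lower at 8 weeks. Over genes well above background on all 5 arrays the correlation of the 2-week transplant was 0.856 with the E13.5 kidney and 0.925 with the P0 kidney, and that of the 4-week transplant was 0.829 with the E13.5 kidney, 0.902 with the P0 kidney and 0.841 with the 8-week kidney. Over all genes the correlation of the 2-week transplant was 0.913 with the E13.5 kidney, 0.945 with the P0 kidney and 0.883 with the 8-week kidney, and that of the 4-week transplant was 0.898 with the E13.5 kidney, 0.930 with the P0 kidney and 0.884 with the 8-week kidney. With Spearman's rho the correlation of the 2-week transplant was 0.866 with the E13.5 kidney, 0.918 with the P0 kidney and 0.830 with the 8-week kidney, and that of the 4-week transplant was 0.840 with the E13.5 kidney, 0.894 with the P0 kidney and 0.833 with the 8-week kidney. For the 4-week transplant against P0, with 2401 genes 4-fold apart, the count was 1495 with normexp, 1499 with maximum likelihood, 6094 at 2-fold and 1063 at 8-fold. For 8 weeks against P0, with 3228, it was 7867 at 2-fold and 1492 at 8-fold.

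Among list medians at least 2-fold apart, those that turned sign with normexp were for P0 against E13.5 -0.19 (early nephron), -1.24 (hepatocyte) and -0.45 (gonad). For 8 weeks against E13.5 they were -0.18 (kidney injury), -0.76 (adipocyte), -0.76 (hepatocyte), -0.63 (gonad), -0.44 (sex-linked) and -0.27 (choroid plexus). For the 2-week transplant against E13.5 they were -1.73 (hepatocyte) and -0.30 (choroid plexus). For the 4-week transplant against E13.5 they were -0.35 (collecting duct principal cell). With maximum likelihood those that turned were for P0 against E13.5 -0.19 (early nephron), -1.25 (hepatocyte) and -0.45 (gonad). For 8 weeks against E13.5 they were -0.19 (kidney injury), -0.76 (adipocyte), -0.77 (hepatocyte), -0.64 (gonad), -0.45 (sex-linked) and -0.27 (choroid plexus). For the 2-week transplant against E13.5 they were -1.75 (hepatocyte) and -0.31 (choroid plexus). For the 4-week transplant against E13.5 they were -0.36 (collecting duct principal cell). Over genes well above background on both arrays, which leaves fewer members, those that turned were for 8 weeks against E13.5 0.35 (neuron), 0.92 (cartilage), -0.71 (urothelium) and 1.62 (adrenal medulla). For the 4-week transplant against E13.5 they were 0.37 (erythroid) and 0.49 (cartilage). For the 4-week transplant against 8 weeks they were 0.83 (B and plasma cell), 11.26 (hepatocyte, the value of Ttr alone) and -0.68 (adrenal medulla).

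The medians at 0 with normexp were for P0 against E13.5 collecting duct intercalated cell, neutrophil, interferon response and choroid plexus, for 8 weeks against E13.5 B and plasma cell and urothelium, for the 2-week transplant against E13.5 loop of Henle, renal endocrine, neutrophil, bone and gonad, and for the 4-week transplant against E13.5 proximal tubule, loop of Henle, glia, bone and gonad. A median is 0 where the bound of a gene not well above background on the E13.5 array passes its value on the other. Of the list medians less than 2-fold apart, 31 turned sign with normexp, 9 with quantile normalization and 10 in the authors' table.

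Signal over background limits the folds of genes not well above background on 1 array, which are lower bounds. Only the 2-week transplant against E13.5, and the comparisons among the P0 kidney, the 8-week kidney and the 4-week transplant, lie within a slide. No paired analysis was possible because each group has 1 array.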

Other observations

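The lists of brown fat, urothelium, choroid plexus, other steroidogenic and fetal skeletal muscle genes below were written after values of many of their members had been seen, and all tests in this part were chosen after the results they concern.

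Brown fat genes were higher in both transplants, in 6 of 7 cases at 2 weeks (median 6.11 against E13.5) and 6 of 7 at 4 weeks (median 7.68). Ucp1, the uncoupling protein of brown fat, was at least 1090.4-fold and at least 1576-fold higher and was not well above background in any of the kidneys. All 10 urothelium genes were higher in the 4-week than in the 2-week transplant (median 4.69), with Upk3a at 49.1-fold and Upk1b at 26.7-fold. Against the P0 kidney of the same slide the median was 2.49, with 9 of 10 higher. Of the choroid plexus genes 8 of 9 were higher at 4 than at 2 weeks (median 3.78), led by Kcne2 (at least 368-fold), Ttr (334-fold) and Kcnj13 (51.6-fold). The kidneys also expressed 8 of the 9 choroid plexus, 10 of the 10 urothelium, 6 of the 8 brown fat and 8 of the 10 other steroidogenic genes above background, such as Sostdc1 at 1.64 in the 8-week kidney. Other steroidogenic genes were higher in 8 of 9 cases (median 2.66), with Akr1b7, also a member of the renal endocrine list, at 34.5-fold and Fdxr at 14.8-fold.

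The E13.5 array carried embryonic globins and muscle genes. Hbb-y lay at 7.78, Hba-x at 4.49 and Hbb-bh1 at 3.87 there, and none was well above background on another array. Of the fetal skeletal muscle genes 7 of 9 were lower at P0 (median -3.51), with Myog at least 17.8-fold lower. Among sex-linked genes, the Y-linked Ddx3y lay at -0.78, -1.40, -0.06 and 0.22 in the E13.5 kidney, the 2-week and 4-week transplants and the 8-week kidney, and was not well above background in the P0 kidney. The X-linked Xist was not well above background in the 8-week kidney and lay at -0.73, -0.93, -1.60 and -2.88 in the E13.5 and P0 kidney and the transplants. Sex therefore cannot be told apart from age or transplantation in comparisons with the P0 or the 8-week kidney.

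Nephron genes lay lower at 4 than at 2 weeks, with a median of -0.79 over 71 genes of 6 segment lists (95% interval over genes -0.96 to -0.54), 25 of them at least 2-fold lower. Under other scalings the medians were -0.88 after quantile normalization and -0.98 in the unshifted authors' table, so that the highest of the 3 scalings was -0.79. Both alternatives also lowered the median over all genes, from -0.003 to -0.08 and -0.19. Leaving out the shift moves all genes alike, so the authors' table could not bring the nephron median to 0. The nephron median lay below that of all genes under each scaling, which argues against a shift common to all genes as the only source. Other effects of scaling were not tested. With background from the negative controls the nephron median was -0.70 (95% interval -0.87 to -0.32), and all 4 intervals lay below 0. These intervals, and those below, treat genes as independent, which they are not. They hold no variation between animals, labellings or slides and do not test a difference between the graft times. A larger share of other cells that lowers all remaining genes alike could account for the lower nephron genes and cannot be told apart: the nephron median lay -0.40 (95% interval over genes -0.59 to -0.17) from that of 44 endothelial, macrophage, T cell and smooth muscle genes (-0.39), but added tissue may bring such cells along. List by list, nephron minus list lay below 0 for smooth muscle (-0.74, 95% interval -1.21 to -0.28), T cells (-0.42, -1.11 to -0.05) and endothelium (-0.38, -0.58 to -0.13). The interval included 0 for macrophages (-0.30, -0.54 to 0.02) and proliferation (-0.20, -0.62 to 0.10). It also did for fetal renal stroma, with a list median of -0.83 (0.04, -0.66 to 0.90), and extracellular matrix, with one of -0.59 (-0.20, -0.50 to 0.34). The transplants lay on different slides, so a difference between slides cannot be told apart from one between graft times. A biological difference between the graft times was not tested and stays open.

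Glia and bone genes were higher in the 2-week transplant than in the E13.5 kidney. In the 4-week transplant, on the other slide, 7 of 9 glia (median 2.13) and 4 of 6 bone genes (median 1.92) were higher too. Neither of these 4-week medians held with a normexp background correction. The 2-week transplant and the E13.5 kidney both lie on slide 1, so a difference between slides is not at issue for them. Brain tissue that brings neurons along may be a source of the glia genes: the neuron list had a median of 0.11 (quartiles -0.63 and 0.57), but all 10 of its genes were well above background in the E13.5 kidney, and such a baseline can hide a small share, so this cannot be told apart from glia without neurons. The neuron gene Snap25 lay at 2.05 in the 2-week transplant and at 1.94 in the E13.5 kidney, and 7 of the 10 glia genes were above background in at least 1 of the kidneys. Neither a source of the bone genes nor a biological explanation was tested.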
